A study of Rattus norvegicus with 9 samples.

How the data were processed

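Total RNA of 9 Sertoli cell cultures, 3 each from rats aged 5, 12 and 60 days, was extracted with RNeasy columns, turned into Cy3-labelled antisense RNA by oligo-dT priming and in vitro transcription, and hybridised to a whole-genome rat oligonucleotide array in the 4x44k format, per the labels. Slides were scanned and spots quantified with Agilent Feature Extraction, per the submitters' processing notes. Per the file headers, the arrays of replicate 1 were read on a G2505B scanner with Feature Extraction 9.5.3.1, and those of replicates 2 and 3 on a G2505C scanner with version 10.5.1.1. The processed signal is an intensity after background subtraction and spatial detrending within the array, per the file headers, with no scaling between arrays. Values of replicate 3 were stored with fewer digits, and the files of replicate 2 hold no mean spot signal and no gene names. The deposited table of the series holds log2 values. Set against the scans, each of its columns equals the log2 processed signal minus one constant, the 75th percentile of the array, within 0.01 for 99.638% to 99.722% of probes. An oligo-dT primed label measures mostly polyadenylated RNA near the 3' end, and a fixed input of RNA hides differences in RNA per cell.

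From the scans, control spots were left out, repeated spots of a probe were averaged, and 254 probes with a quality failure on at least 1 array were left out of 41012. The log2 processed signal was scaled to the 75th percentile of each array, which lay between 148 and 437 intensity units. Probes well above background on at least 2 of the 3 arrays of at least 1 age were kept (26599). Names were brought to current symbols through RefSeq accessions (11053 probes), current symbols (5666) or older symbols (3781), and 20512 probes kept the name in the file. The probe with the highest mean stood for each gene, which left 22448 genes, 11577 of them with a current symbol. Positions are those of the probes in the rn4 build, as the files of replicate 3 give them. No annotation of that build was used, so exons and untranslated regions are not stated. Cyp19a1 was on the array without passing the filter, and Acta2 was not found by name.

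A linear model with a mean per age was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3 (6 residual and 4.637 prior degrees of freedom), followed by 2-sided moderated tests of the 3 pairwise contrasts and a moderated F-test. P values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called, or said to have risen or fallen, at an adjusted p under 0.05. Fold changes of genes that were not well above background on any array of the lower age are given as bounds: in that age, signals under the array's lowest value that was well above background were set to that value, and the fold from there to the mean of the other age is written as at least N-fold. Tables were made with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9.

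Before the data were examined, 20 pathway lists and 9 cell type lists were fixed. The pathway lists were Sertoli identity and secretion, immature Sertoli markers, FSH and cAMP signalling, androgen-responsive Sertoli genes, junction and barrier, cell cycle, CDK inhibitors and exit, sterol biosynthesis, glycolysis and lactate supply, oxidative phosphorylation, basement membrane and matrix turnover, fibrillar matrix, paracrine factors, retinoid pathway, nuclear receptors, phagocytosis and lysosome, glutathione and oxidative defence, interferon and antigen presentation, inflammation, and iron, vitamin and metal carriers. The cell type lists were spermatogonia, spermatocytes, spermatids, Leydig cells, peritubular myoid cells and fibroblasts, macrophages, endothelium, red blood cells, and rete testis and epididymal epithelium (called duct epithelium in the text). Lists were tested with camera at a preset correlation of 0.01, 2-sided, with adjustment over the 29 lists of a contrast, again with an estimated correlation, and with fry, which asks whether the genes of a list move one way on balance and does not compare them with other genes. Camera compares a list with all other genes. Single members were also adjusted over the list alone. Genes to be named were fixed by rule at the same time, for each contrast. They were the 8 largest rises and 8 largest falls among called genes with a symbol, the same direction under every replicate number and unsaturated signal above background on all arrays of both ages. To these came the 3 largest bounds each way, up to 4 members per list, with called members of the largest change first and then the brightest, and 34 genes chosen whatever their change.

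Replicate numbers coincide with slides. Deviations from the age means correlated at 0.181 to 0.601 between arrays of the same number and at 0.094 or less between arrays of different numbers, so the numbers pair the arrays. Arrays of a number share the slide, and whether they also share animals or a culture day is not in the labels, so the source of the pairing stays open. A fit with the number as a block was run as an alternative. The calculation was tested on simulated data: of 100 genes changed 4-fold and 100 changed 8-fold among 22448, limma recovered 44% and 83% for 12 against 5 days, 28% and 71% for 60 against 12 days, and 46% and 76% for 60 against 5 days, with 7, 10 and 6 calls among unchanged genes. The oxidative phosphorylation list was also shifted by 1 (log2). All contrasts used the same means and spreads, so the shares differ between them only through the random draw. Noise was independent between arrays and few genes changed, unlike the real arrays, so these shares need not hold for them. Alternatives were median, quantile and spike-in scaling, the deposited table, a normexp background correction with an offset of 50, no filter and a filter on all 9 arrays, every probe or the mean of a gene's probes, an intensity trend with a robust prior, array weights, the arrays of the 2 ages alone, the replicate block, the slide as a random block, and leaving out each array or replicate number. Normexp was planned on mean spot signals, which 3 files lack, and was run on median signals instead.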

Results

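Sertoli cells, the somatic cells of the seminiferous tubule that nourish germ cells, were taken from the testes of rats aged 5, 12 and 60 days. The cells were kept in culture for 4 days in a defined medium and then received pulses of oFSH (50 ng/ml) and testosterone (1e-07 M) for 11 h. Each age was measured on 3 one-colour expression arrays, so that 9 arrays of 41012 probes were available, and no culture without hormones was among them. The comparisons therefore ask how the transcriptome of hormone-treated Sertoli cells differed between ages that span postnatal maturation of the testis. Between 49.1% and 63.0% of the probes of an array lay well above background, and 29 to 141 probes per array were saturated. The number of arrays limits the precision of each value. Each slide carried 1 array of every age under the same replicate number, and the position on the slide was the same for all arrays of an age, so position and age cannot be told apart. The labels do not say whether the replicates were separate animals or cultures, and the p values measure the spread between these samples.

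Arrays of the same age resembled each other most. Across the 22448 genes tested, Pearson's r between arrays of the same age lay between 0.94 and 0.97. It was 0.90 to 0.94 between 5 and 12 days, 0.85 to 0.87 between 12 and 60 days and 0.78 to 0.81 between 5 and 60 days, computed across genes, which are not independent replicates. The first principal component held 58.8% of the variance and ordered the arrays by age. Over the 3 ages, 8233 genes changed in the moderated F-test of limma (36.7% of those tested), and without replicate 2 the number was 4868. Levels below are log2 signals relative to the 75th percentile of the array, fold changes are log2 values with their standard error from the model of all 9 arrays, and adjusted p values are from limma.

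The signals of the spike-in controls answer to synthetic RNA and not to rat genes. On the scale of the 75th percentile they differed between ages, by amounts that were not the same on every slide. The labels do not say how that RNA was added. Across the 8 that were measured, the median shift was 1.25 from 5 to 12 days (0.30 to 1.43), -1.001 from 12 to 60 days (-1.15 to -0.59) and 0.24 from 5 to 60 days (-0.28 to 0.41). The values 0.30, -0.59 and -0.28 came from the brightest control, whose saturation was not checked. The others ran from 0.90 to 1.43, from -1.15 to -0.70 and from 0.04 to 0.41. These ranges are across controls, and the slides differed more. On slides 1, 2 and 3 the median shift was 2.092, -0.005 and 1.655 from 5 to 12 days. It was -1.142, -0.284 and -1.624 from 12 to 60 days and 0.924, -0.285 and 0.018 from 5 to 60 days. With the median of the controls as the scale of each array, every fold change and list median moves by the same amount. That amount was -1.28, 0.94 and -0.34 in these comparisons. The median log2 fold change of all genes was then -1.24, 0.78 and -0.43, against 0.05, -0.16 and -0.09, so directions below are relative to the other genes of the array.

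**Figure D1:**
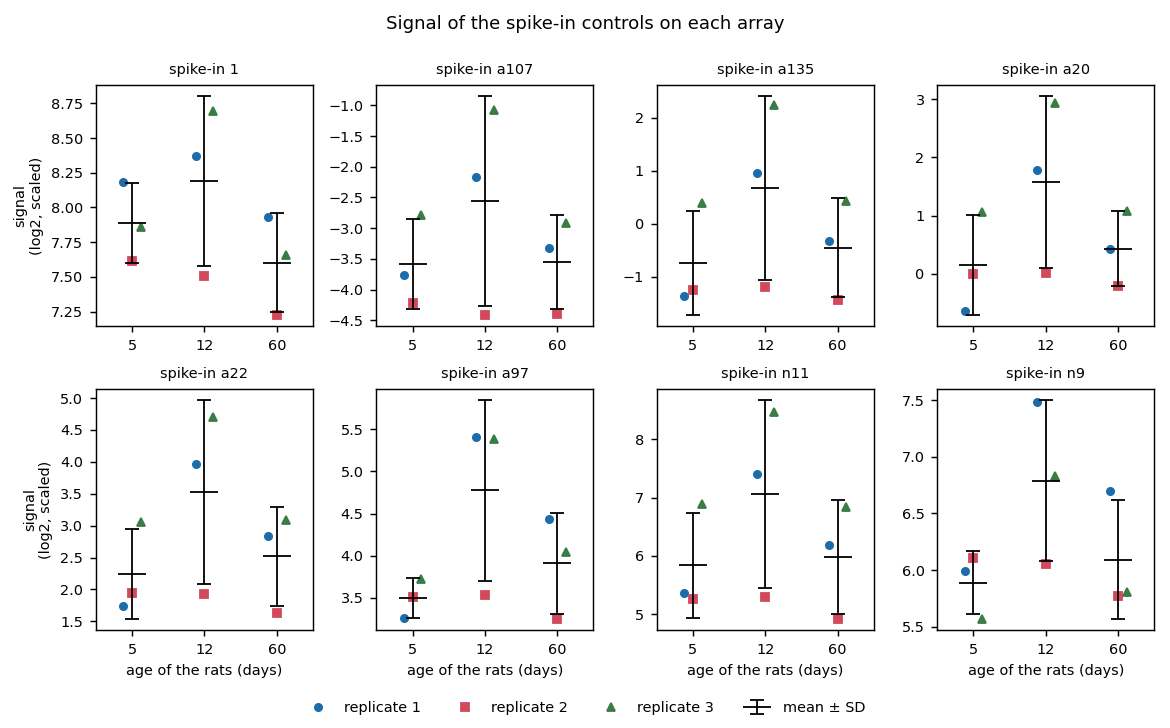
Log2 signal of the 8 spike-in controls on each of the 9 arrays, relative to the 75th percentile of the array, against age in days. Points are arrays and bars the mean and SD of the 3 arrays of an age. The median shift between 5 and 12 days was 2.09 on slide 1, -0.01 on slide 2 and 1.66 on slide 3.

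The comparison of 12 with 5 days covers the prepubertal phase. Of 26 genes of Sertoli cell identity and secretion, 17 rose: Tf, which encodes the iron carrier transferrin, rose by 2.89 ± 0.31 (adjusted p = 0.000217), and Inha, the alpha subunit of the hormone inhibin, by 2.72 ± 0.30 (adjusted p = 0.000251). Of 26 spermatocyte markers 13 rose, among them Sycp3, a part of the synaptonemal complex, which was at least 14.0-fold higher at 12 days. Falls were seen in 12 of 29 fibrillar matrix, 11 of 18 macrophage and 6 of 10 duct epithelium genes, such as Lum, which encodes the collagen-binding proteoglycan lumican and fell by 5.82 ± 0.46 (adjusted p = 4.22e-05). Amh, the anti-Müllerian hormone of the immature Sertoli cell, was not called (0.30 ± 0.31, adjusted p = 0.658). In all, 1379 genes rose and 1423 fell (12.5% of those tested), and 2801 of these 2802 differed at least 2-fold.

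In the list of Sertoli identity and secretion, 17 of 26 measured members rose and 9 were not called (19 rose and 1 fell when adjusted over the list alone), with a median log2 fold change of 2.14. The list lay above the other genes (camera adjusted p = 9.48e-11, and adjusted p = 0.0265 with an estimated correlation). The transcription factors Dmrt1 (3.39 ± 0.41) and Sox9 (2.50 ± 0.41), the androgen carrier Shbg (2.50 ± 0.32) and the inhibin subunit Inhbb (2.41 ± 0.33) rose. So did Cst12 (3.37 ± 0.40) and Fabp9 (2.84 ± 0.40), and the protein of the latter is known from the sperm head. Of the 26 members, 13 stand in another list as well. Cldn11, a claudin of the blood-testis barrier, rose by 2.12 ± 0.40 (adjusted p = 0.00593, but 0.0674 without replicate 2). Gata1 was well above background on 1 of 3 arrays at 12 days and on 0 of 3 at 5 days, so its rise is given without a size (adjusted p = 0.00904, but up to 0.0851 without a replicate number). Fshr, the receptor of FSH, rose by 1.86 ± 0.50 (adjusted p = 0.0343), a call lost without either array of replicate 1, the 5-day array of replicate 2 or the 12-day array of replicate 3 (adjusted p up to 0.132), without the filter (0.0512) or with the 6 arrays of both ages alone (0.0609). Clu, the secreted chaperone clusterin, rose by 1.06 ± 0.31 (adjusted p = 0.0469), a call lost without any array other than the 12-day array of replicate 2 and the 60-day array of replicate 1 (adjusted p up to 0.141). Clu was also not called with median scaling (adjusted p = 0.0581), with every probe tested (0.0513), without the filter (0.0998) or with the 6 arrays of both ages alone (0.0851), and its direction turned with the spike-in scale (-0.22, adjusted p = 0.84). Wt1 (0.92 ± 0.62) and Gata4 (1.04 ± 0.39) were not called, and Gata4 was with the replicate number as a block (adjusted p = 0.0441).

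Germ cell markers rose beside the Sertoli genes. Of the 26 spermatocyte markers measured, 13 rose and 13 were not called (15 rose and 1 fell when adjusted over the list alone), with a median of 1.55, or 1.38 with the 6 members near background at their bound. Their camera adjusted p was 2.46e-09, and adjusted p = 0.0778 with an estimated correlation. Tex101 was at least 47.4-fold higher at 12 days (rn4 chromosome 1, 79948321 to 79948808), Sycp2 at least 10.4-fold and Sycp1 at least 6.06-fold. Among 10 spermatogonial markers, 6 rose and 1 fell, the same counts as when adjusted over the list alone (median 1.72, adjusted p = 0.00115, and adjusted p = 0.195 with an estimated correlation). The RNA helicase Ddx4 was at least 7.44-fold higher and Taf7l rose by 5.92 ± 0.42, while Gfra1, the receptor for the niche factor GDNF on stem spermatogonia, fell by 2.38 ± 0.37. Of the 35 spermatid markers, 1 rose and 1 fell, and the list was not called (median 0.14, adjusted p = 0.335). The largest rises among genes measured above background at both ages held Erhl1 (4.95 ± 0.39) and the meiotic gene Tex15 (4.64 ± 0.35, rn4 chromosome 16, 62380099 to 62380158). They also held the nuclear receptor Nr4a3 (4.53 ± 0.36), the vasoconstrictor endothelin, Edn1 (4.40 ± 0.41), Gpat2 (4.40 ± 0.35), Ppp1r14c (3.91 ± 0.33), Tmem74 (3.85 ± 0.36) and Fkbp6 (3.84 ± 0.34). From background, Rhoxl was at least 22.2-fold and Ccnb1ip1, which acts in meiotic crossing over, at least 19.4-fold higher.

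Part of the connective tissue genes fell over the same interval. In the fibrillar matrix list, 12 of 29 members fell and 17 were not called (1 rose and 13 fell when adjusted over the list alone; median -1.15, adjusted p = 1.27e-08, and adjusted p = 0.127 with an estimated correlation). Besides Lum, the proteoglycan Dcn fell by 5.61 ± 0.48 and Efemp1 was at least 15.8-fold lower. Thbs2 fell by 6.61 ± 1.29 (adjusted p = 0.00675), a call lost without replicate 1 or 2 (adjusted p up to 0.119). Other large falls were those of the claudin Cldn9 (-6.34 ± 0.64), Itm2a (-6.05 ± 0.51), Plac8 (-5.75 ± 0.40) and the complement protease C1s (-5.06 ± 0.32). To background, Kng2 and its near-identical paralog Kng1 were at least 93.2-fold and 69.5-fold lower, and Upk1b at least 46.1-fold. Of 29 genes of basement membrane and matrix turnover, 2 rose and 8 fell (2 and 10 when adjusted over the list alone; median -0.60, adjusted p = 0.000543, and adjusted p = 0.195 with an estimated correlation). The proteases Mmp2 (-2.76 ± 0.42) and Adamts5 (-2.65 ± 0.39) were among those that fell. Of the markers of peritubular myoid cells and fibroblasts, 5 of 24 fell and 19 were not called (6 fell when adjusted over the list alone). Their median fold change was -0.15 (camera adjusted p = 0.00756, and adjusted p = 0.492 with an estimated correlation), and 7 of the 24 belong to other lists. The median level of the list nevertheless went from 4.53, 4.62 and 4.69 on the 5-day arrays of replicates 1, 2 and 3 to 2.82, 3.38 and 3.14 at 12 days. Duct epithelium markers went down as well, with 1 of 10 rising and 6 falling (1 and 7 when adjusted over the list alone; median -2.20, adjusted p = 0.000543, and adjusted p = 0.0778 with an estimated correlation). The keratin gene Krt7 (-4.77 ± 0.82), E-cadherin, Cdh1 (-4.20 ± 0.50), and Cldn4 (-2.89 ± 0.36) fell.

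Of 18 macrophage markers, 11 fell and 7 were not called (12 fell when adjusted over the list alone; median -2.04, adjusted p = 1.16e-07, and adjusted p = 0.0721 with an estimated correlation). The Fc receptor Fcgr2b fell by 3.79 ± 0.34, Aif1 by 3.50 ± 0.47 and lysozyme, Lyz2, by 2.67 ± 0.42. In the inflammation list, 7 of 21 fell and 14 were not called (13 fell when adjusted over the list alone; median -1.32, adjusted p = 2e-07, and adjusted p = 0.0374 with an estimated correlation). Serping1, the inhibitor of complement C1, fell by 4.58 ± 0.38 and complement factor B, Cfb, was at least 12.2-fold lower. Of 32 interferon and antigen presentation genes, 4 fell and 28 were not called, as when adjusted over the list alone (median -0.48, adjusted p = 0.00773, and adjusted p = 0.53 with an estimated correlation). The chemokine gene Cxcl10 fell by 3.56 ± 0.61. The phagocytosis and lysosome list had 5 of 33 members lower and 28 not called (6 lower when adjusted over the list alone; median -0.51, adjusted p = 0.0102, and adjusted p = 0.0778 with an estimated correlation). Its call was lost without the array of replicate 2 at 5 days or of replicate 3 at 12 days (adjusted p up to 0.057) and with the spike-in controls as the scale (adjusted p = 0.0801). Of 6 red cell markers, 2 fell and 4 were not called (4 fell when adjusted over the list alone; median -1.27, adjusted p = 0.00213, and adjusted p = 0.0778 with an estimated correlation). Endothelial markers were not called as a list (1 rose and 4 fell of 13, median -1.14, camera adjusted p = 0.128), but were with the spike-in scale (camera adjusted p = 0.0259). Ramp2 fell by 2.19 ± 0.35.

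Sterol biosynthesis genes were slightly lower: 2 of 26 fell and 24 were not called (1 fell when adjusted over the list alone; median -0.53, adjusted p = 0.00619, and adjusted p = 0.0778 with an estimated correlation). That call was lost without the 5-day array of replicate 2 (adjusted p = 0.0548) and with the spike-in scale (adjusted p = 0.102). The other lists were not called. Cell cycle genes stayed uncalled in limma in all 71 cases, with 5 at an unadjusted p under 0.05, and Cdk1 stood at 0.11 ± 0.36. The same held for the 39 genes of oxidative phosphorylation, with 1 at that level. Among immature Sertoli markers, 3 rose and 6 fell of 23, with Cited1 up by 2.77 ± 0.29 and Igf2 down (-3.30 ± 0.35); their median was 0.01, their mean -0.46 and the test pointed down. Of 42 FSH and cAMP genes, 5 rose and 8 fell (median -0.04, mean 0.12, test up), and the phosphodiesterase Pde4d rose by 2.97 ± 0.38. Of 17 androgen-responsive genes, 4 rose and 2 fell (median -0.32, mean 0.08, test down), with Tsx up by 2.62 ± 0.35. In the junction list, 9 of 43 rose and 5 fell, including Pard6b (3.1 ± 0.43) and Cldn1 (-3.56 ± 0.45). Of 50 paracrine factors, 11 rose and 12 fell, with Igfbp4 (-5.04 ± 0.60) and the chemokine Cxcl12 (-4.54 ± 0.59) among the latter. In the retinoid list, 3 of 20 rose and 5 fell, the binding proteins Crabp1 (2.77 ± 0.45) and Crabp2 (-3.61 ± 0.36) in opposite directions. Nuclear receptors rose in 7 of 27 cases and fell in 2, glutathione genes in 2 and 4 of 32 and iron, vitamin and metal carriers in 4 and 3 of 18. The CDK inhibitors had 4 rises and 3 falls among 18, glycolysis 1 and 1 among 26 and Leydig cell markers 3 and 5 among 16. Examples are Nr2f1 (-3.02 ± 0.46), Nqo1 (-3.20 ± 0.42), Cdkn2b (-3.20 ± 0.38) and Hsd11b1 (-4.59 ± 0.44).

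The count of 2802 was 1680, 1052 and 1637 without replicate 1, 2 or 3 and 1865 without the 5-day array of replicate 2. With the spike-in controls as the scale, chosen after the data were seen, 93 genes were higher and 2139 lower, and 33 of the 50 named genes that rose, but 0 of the 71 that fell, lost their call. Those that lost it included Tf, Inha, Inhbb, Shbg, Sox9, Dmrt1, Cst12, Fabp9, Cldn11, Fshr and Gata1. The Sertoli median was then 0.86 (-0.37, 2.11 and 0.52 on slides 1, 2 and 3) and that of spermatocytes 0.26 (-0.84, 2.17 and 0.17), so neither rise held on every slide. Fry did not call the interferon (adjusted p = 0.226) and peritubular (0.131) lists. With only probes well above background on all 9 arrays, the spermatocyte (0.448) and peritubular (0.0516) lists lost their calls, and with normexp that of red cell markers was lost (up to 0.174). Sizes are less certain for genes dim at the lower age: Fabp9, Cldn1, Taf7l and Fshr were well above background there on 1 of 3 arrays, and Cst12, Fcgr2b and Aif1 on 2.

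**Figure D2:**
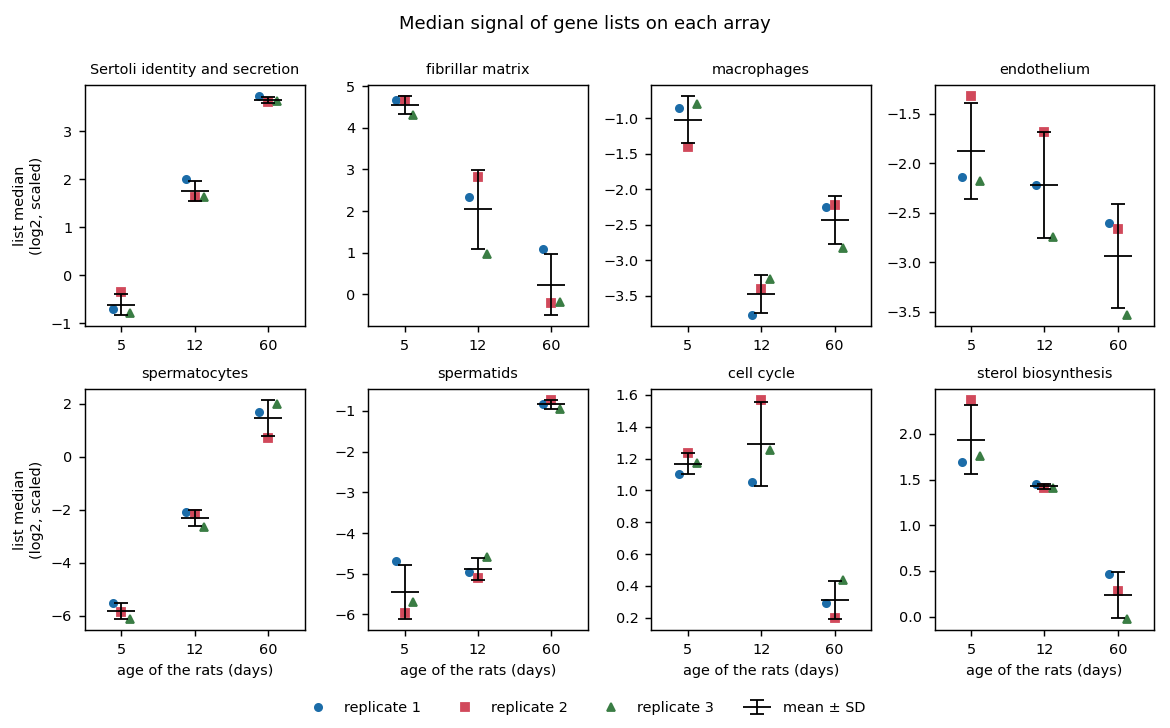
Median log2 signal of 8 gene lists on each array, relative to the 75th percentile of the array, against age in days. Points are arrays and bars the mean and SD of the 3 arrays of an age. Sertoli genes changed by a median of 2.14 from 5 to 12 days, and spermatid markers by 3.94 from 12 to 60 days. With the spike-in controls as the scale the median of the cell cycle list from 12 to 60 days was 0.16 in place of -0.78. The spike-in shift in that interval was -1.142, -0.284 and -1.624 on slides 1, 2 and 3.

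The comparison of 60 with 12 days spans puberty. Of 26 spermatocyte and 35 spermatid markers, 25 and 31 rose, with the highest list medians. Ldhc, the lactate dehydrogenase of the testis, rose by 8.39 ± 0.41 (adjusted p = 2.58e-06; rn4 chromosome 1, 97433896 to 97435065), and Smcp, a protein of the sperm mitochondrial sheath, was at least 63.2-fold higher. Of the Sertoli genes, Clu rose by 2.87 ± 0.31 (adjusted p = 7.66e-05) and Gata1, a transcription factor of the mature Sertoli cell, by 3.53 ± 0.38 (adjusted p = 7.4e-05). Rises were seen in 15 of 32 interferon genes, and falls relative to the rest in 19 of 29 fibrillar matrix, 12 of 24 peritubular, 13 of 26 sterol and 24 of 71 cell cycle genes; none of these lists was called with an estimated correlation. The troponin gene Tnnt2 (-7.83 ± 0.52, adjusted p = 5.48e-06) and the cyclin gene Ccnd2 (-4.58 ± 0.68, adjusted p = 0.000589) fell. In all, 2753 genes rose and 2934 fell (25.3% of those tested), 5619 of these 5687 at least 2-fold.

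Spermatocyte markers rose in 25 of 26 cases, as when adjusted over the list alone, with a median of 3.68, or 3.45 with members near background at their bound (adjusted p = 3.28e-22, and adjusted p = 0.069 with an estimated correlation). Sycp3 rose by 4.13 ± 0.33, and Pgk2, the glycolytic kinase of germ cells, was at least 16.7-fold higher. Of 35 spermatid markers, 31 rose and 4 were not called (32 rose when adjusted over the list alone; median 3.94, or 2.60 with 18 members at their bound; adjusted p = 5.64e-24, and adjusted p = 0.069 with an estimated correlation). The transition protein gene Tnp1 rose by 6.07 ± 0.63 and the protamine gene Prm1 by 3.49 ± 0.49, both packing proteins of sperm DNA. Spermatogonial markers rose in 4 of 10 cases, as when adjusted over the list alone (median 0.49, adjusted p = 0.0369, and adjusted p = 0.344 with an estimated correlation). That list's call was lost without either of the 12-day arrays of replicates 1 and 3 or the 60-day array of replicate 1 (adjusted p up to 0.102). Ddx4 rose by 3.16 ± 0.37. The largest rises above background at both ages were led by Ldhc, Fabp9 (7.98 ± 0.40), the citrate carrier Slc13a5 (7.17 ± 0.59) and Igsf1 (6.60 ± 0.40). Efcab10 (6.31 ± 0.51), Emb (6.30 ± 0.45), Plaat1 (6.16 ± 0.45) and Qrich2 (6.13 ± 0.38) followed. From background, Hspb9 was at least 312-fold, the water channel Aqp8 at least 218.7-fold and Mroh2b at least 213-fold higher.

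Beside the germ cell markers, Sertoli identity genes rose in 9 of 26 cases and fell in 2, as when adjusted over the list alone (median 0.74, adjusted p = 0.00548, and adjusted p = 0.124 with an estimated correlation). The cystatin-related Cst9l rose by 5.82 ± 0.45 and Cst12 by 3.74 ± 0.40; Fabp9, the sperm protein, is a member too. Tf (1.46 ± 0.31), Shbg (1.57 ± 0.32) and Cldn11 (2.03 ± 0.40) rose, with adjusted p of 0.108, 0.0981 and 0.0699 without replicate 2. Fshr (0.91 ± 0.50), Sox9 (-0.08 ± 0.41) and Inha (-0.48 ± 0.30) were not called. Of 23 immature Sertoli markers, 1 rose and 10 fell (2 and 11 when adjusted over the list alone; median -0.81, adjusted p = 0.028, and adjusted p = 0.124 with an estimated correlation), a call lost without the 60-day array of replicate 3 (adjusted p = 0.07). Lhx9, a homeobox gene of the early gonad, fell by 3.61 ± 0.41 and Id1 by 2.40 ± 0.37, while Ptgds rose by 4.50 ± 0.39. Amh fell by 1.1 ± 0.31 (adjusted p = 0.023), a call lost without any 12-day array or without the 60-day array of replicate 3 (adjusted p up to 0.0911) and with the spike-in scale (-0.16, adjusted p = 0.933).

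Cell cycle genes fell in 24 of 71 cases and rose in 3 (27 and 3 when adjusted over the list alone; median -0.78, adjusted p = 0.00026, and adjusted p = 0.0712 with an estimated correlation), including the replication licensing factor Cdt1 (-2.73 ± 0.44); the spindle gene Tpx2 rose by 2.60 ± 0.39. Mki67 stood at 0.06 ± 0.55 and Ccnb1 at -0.67 ± 0.40, both uncalled. Sterol biosynthesis genes fell in 13 of 26 cases and 13 were not called (15 fell when adjusted over the list alone; median -1.19, adjusted p = 0.000695, and adjusted p = 0.069 with an estimated correlation). The reductase gene Tm7sf2 fell by 2.44 ± 0.32 and Acat2 by 1.86 ± 0.31. With the spike-in scale the medians of the cell cycle (0.16), basement membrane (0.18) and immature Sertoli (0.14) lists lay above 0. Those of the sterol (-0.25) and paracrine (-0.08) lists lay close to it. These values pool the slides, and the spike-in shift was -1.142, -0.284 and -1.624 on slides 1, 2 and 3. On slides 1 and 3 that shift exceeded in size the fall of each of these lists on the 75th percentile scale. On slide 2 it was smaller than the falls of the cell cycle (-1.006), sterol (-1.24), paracrine (-1.108), basement membrane (-0.743) and immature Sertoli (-0.645) lists. Only on slide 2, then, did these falls go beyond the spike-in shift. The calls of the immature Sertoli (adjusted p = 0.0854), spermatogonial (0.0713) and phagocytosis (0.17) lists were lost on the spike-in scale.

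Matrix genes fell further. In the fibrillar matrix list, 1 of 29 rose and 19 fell (2 and 20 when adjusted over the list alone; median -1.89, adjusted p = 6.36e-07, and adjusted p = 0.174 with an estimated correlation), including Ogn (-5.39 ± 0.48), the elastic fibre gene Fbln5 (-5.71 ± 0.47) and Mfap4 (-4.48 ± 0.38). Of the basement membrane genes, 3 of 29 rose and 12 fell, as when adjusted over the list alone (median -0.76, adjusted p = 0.0134, and adjusted p = 0.295 with an estimated correlation), with the collagen gene Col4a1 at -3.67 ± 0.55 and fibronectin, Fn1, at -3.24 ± 0.55. Peritubular markers had 1 rise and 12 falls among 24 (1 and 15 when adjusted over the list alone; median -1.71, adjusted p = 3.23e-05, and adjusted p = 0.295 with an estimated correlation). The smooth muscle actin gene Actg2 fell by 4.67 ± 0.57 and the growth factor receptor gene Pdgfrb by 4.50 ± 0.45. Paracrine factors had 3 rises and 19 falls among 50 (4 and 22 when adjusted over the list alone; median -1.02, adjusted p = 0.000204, and adjusted p = 0.069 with an estimated correlation), with Bmp4 (-4.43 ± 0.39), Nppc (-4.33 ± 0.40) and Igf1 (-3.94 ± 0.44) lower. The largest falls above background at both ages were those of Tnnt2 (rn4 chromosome 13, 48885154 to 48885588), Tnnc1 (-6.09 ± 0.31), Ogn and Cspg4 (-5.28 ± 0.95). Ltbp4 (-5.02 ± 0.48), Plac9 (-4.91 ± 0.37), Adcy2 (-4.72 ± 0.50) and Ppp1r14c (-4.71 ± 0.33) followed. To background, Stc1 was at least 34.4-fold, Pcdh18 at least 27.9-fold and Tmem255b at least 24.4-fold lower.

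Interferon and antigen presentation genes rose in 15 of 32 cases and 17 were not called (20 rose when adjusted over the list alone; median 1.64, adjusted p = 4.22e-08, and adjusted p = 0.228 with an estimated correlation). Irf7 rose by 4.77 ± 0.74, Isg15 by 3.66 ± 0.51 and Mx2 by 3.84 ± 0.56. The median was 0.95, 2.46 and 1.79 on slides 1, 2 and 3. Macrophage markers rose beside them in 7 of 18 cases and fell in 1, as when adjusted over the list alone (median 0.82, adjusted p = 0.00923, and adjusted p = 0.222 with an estimated correlation), with Lcp1 up by 3.28 ± 0.43 and Aif1 by 2.79 ± 0.47. Phagocytosis and lysosome genes rose in 7 of 33 cases and fell in 2, as when adjusted over the list alone (median 0.33, adjusted p = 0.028, and adjusted p = 0.124 with an estimated correlation), including Psap (2.18 ± 0.37) and Hexa (1.88 ± 0.33), which encode lysosomal proteins. That call was lost without the 12-day array of replicate 3 (adjusted p = 0.0602). Glutathione genes rose in 8 of 32 cases and fell in 1 (9 and 1 when adjusted over the list alone; median 0.23, adjusted p = 0.028, and adjusted p = 0.344 with an estimated correlation), with the transferase gene Gsta2 up by 8.60 ± 0.73 and the metallothionein gene Mt1 by 2.06 ± 0.31; without replicate 3 the list had an adjusted p of 0.0633. Retinoid genes rose in 5 of 20 cases and 15 were not called, as when adjusted over the list alone (median 0.50, adjusted p = 0.0398, and adjusted p = 0.155 with an estimated correlation). That call was lost without the 12-day arrays of replicate 1 or 2 or the 60-day array of replicate 3 (adjusted p up to 0.0811). Dhrs3, a retinal reductase, rose by 2.69 ± 0.45 and the retinoic acid hydroxylase Cyp26a1 was at least 3.01-fold higher. Duct epithelium markers rose in 6 of 10 cases and fell in 2, as when adjusted over the list alone (median 1.71, adjusted p = 0.0327, and adjusted p = 0.228 with an estimated correlation), a call lost without the 60-day array of replicate 1 (adjusted p = 0.126). Aqp9 was at least 39.0-fold and Krt19 at least 18.8-fold higher.

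The other lists were not called in this interval. FSH and cAMP genes rose in 2 of 42 cases and fell in 9, with Nr4a3 at -3.42 ± 0.36. Androgen-responsive genes had 4 rises and 2 falls among 17, junction genes 9 and 6 among 43 (Cxadr -3.33 ± 0.39, Jup 2.76 ± 0.42) and CDK inhibitors 2 and 4 among 18. Glycolysis genes had 4 rises and 4 falls among 26 (Eno2 -3.23 ± 0.60), with a median and a mean of -0.06 against a test that pointed up, and oxidative phosphorylation had 1 rise among 39. Nuclear receptors rose in 2 and fell in 7 of 27 cases, Pparg up by 3.29 ± 0.46 and Nr2f1 down (-4.29 ± 0.46). Inflammation genes had 8 rises and 3 falls among 21, with a median of -0.11, a mean of 0.92 and a test that pointed up (adjusted p = 0.115); the chemokine Ccl5 was at least 167-fold higher. Metal carriers had 3 rises and 1 fall among 18, with cubilin, Cubn, at least 10.2-fold higher. Leydig cell markers had 3 and 3 among 16, endothelial markers 1 and 5 among 13 (Kdr -3.35 ± 0.49) and red cell markers 2 and 2 among 6, where the heme enzyme Alas2 rose by 5.70 ± 0.39.

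No list of this interval was called by camera with an estimated correlation, against 17 with the preset one and 24 with fry, and the count of 5687 genes was 3041 without replicate 2 and 3682 without replicate 3. With the spike-in scale, 2619 genes were higher and 399 lower, and 3 of 75 named rises and 27 of 60 named falls lost their call, those of Tm7sf2, Acat2, Cdt1, Id1, Fn1 and Eno2 among them. With only probes well above background on all 9 arrays, 5 lists lost their calls: Sertoli identity (adjusted p = 0.0974, median -0.08), immature Sertoli (0.0638), macrophages (0.907, median -0.28), duct epithelium (0.0638) and retinoid genes (0.112). The immature Sertoli list also lost it without the filter (0.053), retinoid genes with quantile scaling (0.0533), and duct epithelium and spermatogonia with array weights (both 0.0695). Normexp ended the calls of the immature Sertoli, macrophage and retinoid lists (adjusted p up to 0.173). Pparg was not called in the deposited table (adjusted p = 0.12), nor was Col4a1 with the mean of its probes (0.0517). At the lower age, Gata1, Fbln5, Bmp4, Pparg, Gsta2, Tnp1 and Lcp1 were well above background on 1 of 3 arrays, and Nppc and Aif1 on 2, which leaves the sizes of their changes less certain.

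**Figure D3:**
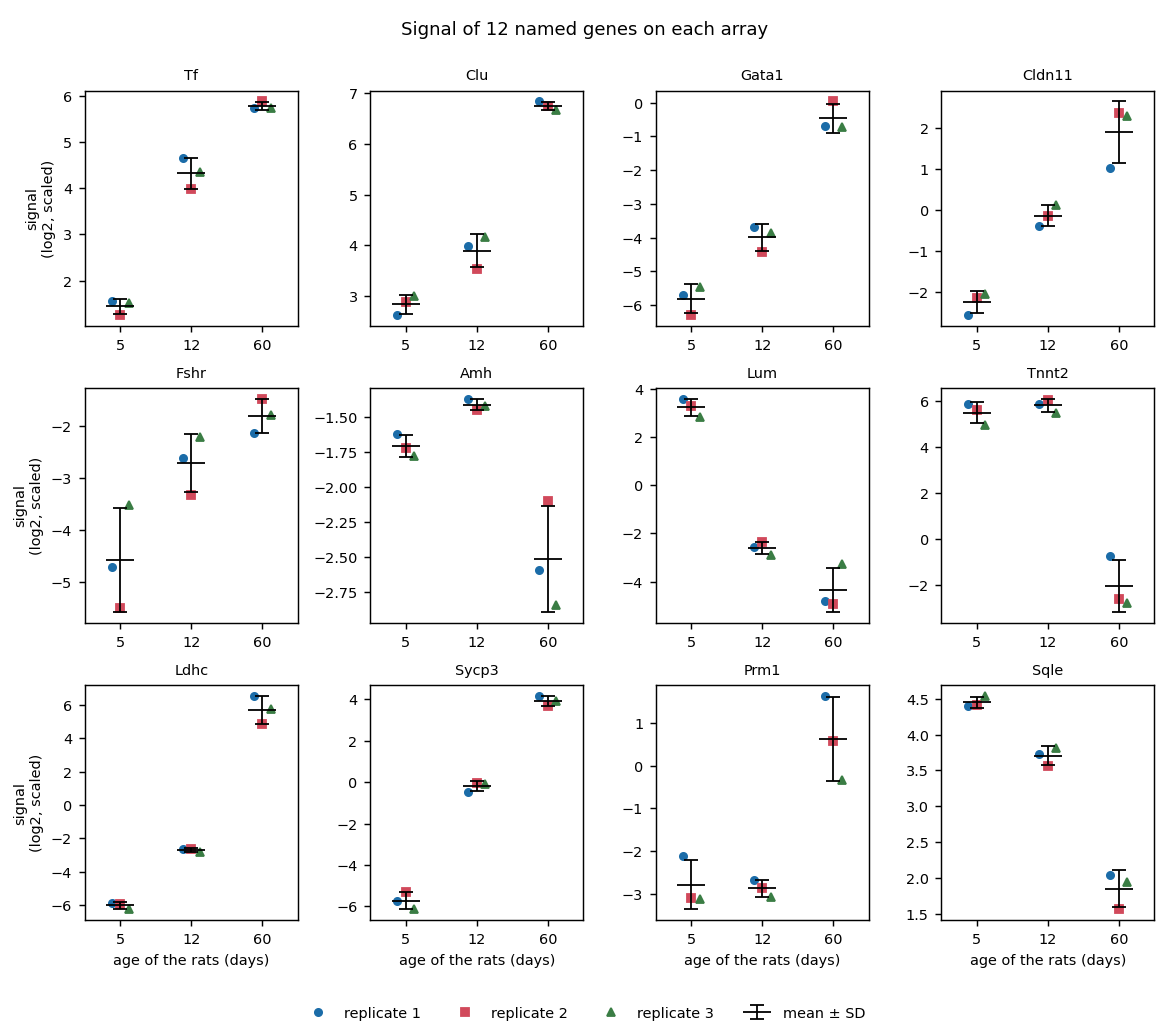
Log2 signal of 12 named genes on each array, relative to the 75th percentile of the array, against age in days. Points are arrays and bars the mean and SD of the 3 arrays of an age. Ldhc changed by 8.39 and Tnnt2 by -7.83 between 12 and 60 days; with the spike-in controls as the scale Clu was at -0.22 rather than 1.06 between 5 and 12 days.

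The comparison of 60 with 5 days sets the adult against the neonatal state. Of the Sertoli genes, Tf rose by 4.35 ± 0.31 (adjusted p = 2.33e-06), Shbg by 4.07 ± 0.32 (adjusted p = 4.38e-06), Cldn11 by 4.15 ± 0.40 (adjusted p = 1.79e-05) and Clu by 3.93 ± 0.31 (adjusted p = 4.28e-06). Germ cell transcripts rose most, with Ldhc at least 833-fold and Sycp3 at least 245.4-fold higher (rn4 chromosome 7, 25164754 to 25165852). Falls were seen in 23 of 29 fibrillar matrix and 18 of 26 sterol genes. Cilp, which encodes a protein of the cartilage matrix, fell by 9.20 ± 0.55 (adjusted p = 1.07e-06; rn4 chromosome 8, 69516933 to 69516992) and the squalene epoxidase Sqle by 2.60 ± 0.29 (adjusted p = 5.02e-05). In all, 3885 genes rose and 4058 fell (35.4% of those tested), 7773 of these 7943 at least 2-fold.

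Of 26 Sertoli identity genes, 18 rose and 1 fell (19 and 1 when adjusted over the list alone), with a median of 2.45 (adjusted p = 4.21e-09, and adjusted p = 0.034 with an estimated correlation). Cst9l rose by 8.06 ± 0.45, Cst12 by 7.10 ± 0.40, and Gata1 was at least 11.7-fold higher; the sperm protein gene Fabp9 rose by 10.82 ± 0.40. Fshr rose by 2.78 ± 0.50 (adjusted p = 0.0013), Inha by 2.24 ± 0.30 and Sox9 by 2.41 ± 0.41. Amh (-0.81 ± 0.31, adjusted p = 0.0652) and Wt1 (1.70 ± 0.62, adjusted p = 0.0549) were not called, but were with the replicate number as a block (adjusted p = 0.044 and 0.00195). Immature Sertoli markers rose in 4 of 23 cases and fell in 10 (4 and 13 when adjusted over the list alone; median -1.23, adjusted p = 0.0442, and adjusted p = 0.161 with an estimated correlation), with Lhx9 at -6.12 ± 0.41 and Id3 at -4.75 ± 0.48. That call was lost without the 5-day arrays of replicates 2 or 3 or the 60-day array of replicate 3 (adjusted p up to 0.083).

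Spermatocyte markers rose in 25 of 26 cases, as when adjusted over the list alone (median 6.02, or 4.81 with 15 members at their bound; adjusted p = 5.5e-21, and adjusted p = 0.034 with an estimated correlation). Spermatid markers rose in 31 of 35 cases, as when adjusted over the list alone (median 3.98, or 3.05 with 22 members at their bound; adjusted p = 4.86e-18, and adjusted p = 0.104 with an estimated correlation), and spermatogonial markers in 7 of 10 with 1 fall, as when adjusted over the list alone (median 2.72, adjusted p = 0.00229, and adjusted p = 0.227 with an estimated correlation). Tex101 was at least 190.5-fold, Ddx4 at least 66.6-fold and Tnp1 at least 35.4-fold higher. Erhl1 (7.68 ± 0.39), the dynein subunit Dync1i1 (7.31 ± 0.36), Ccl5 (6.87 ± 0.77) and Gpat2 (6.65 ± 0.35) led the rises measured above background at both ages. Efcab10 (6.36 ± 0.51), Emb (6.30 ± 0.45), Igsf1 (6.17 ± 0.40) and Spdya (6.16 ± 0.35) followed, and Fam228a was at least 219.9-fold higher.

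Fibrillar matrix genes fell in 23 of 29 cases and 6 were not called (27 fell when adjusted over the list alone; median -4.47, adjusted p = 1.57e-12, and adjusted p = 0.109 with an estimated correlation), among them Ogn (-7.57 ± 0.48), Mfap4 (-7.26 ± 0.38) and Lum (-7.55 ± 0.46). Basement membrane genes had 1 rise and 16 falls among 29, as when adjusted over the list alone (median -1.36, adjusted p = 6.72e-05, and adjusted p = 0.161 with an estimated correlation), with Lama2 at -5.30 ± 0.39 and Mmp2 at -5.31 ± 0.42. Peritubular markers had 1 rise and 16 falls among 24 (1 and 18 when adjusted over the list alone; median -2.67, adjusted p = 3.17e-06, and adjusted p = 0.289 with an estimated correlation), with Pdgfra at -7.56 ± 0.69 and Dcn at -6.09 ± 0.48. On slides 1, 2 and 3 the median was -1.49, -3.16 and -3.07 for peritubular markers, -3.31, -4.84 and -5.01 for fibrillar matrix and -0.65, -1.82 and -1.85 for basement membrane genes. The 60-day array of replicate 1 stood apart, with a peritubular level of 1.55 against -0.06 and -0.43 on the other 60-day arrays, and had the lowest array weight (0.44). Paracrine factors had 9 rises and 22 falls among 50 (10 and 25 when adjusted over the list alone; median -0.97, adjusted p = 0.0053, and adjusted p = 0.113 with an estimated correlation), with Cxcl12 at -8.32 ± 0.59 and Igf1 at -6.81 ± 0.44. Among the largest falls were also Tnnt2 (-7.51 ± 0.52), Adcy2 (-7.36 ± 0.50) and Nr2f1 (-7.30 ± 0.46). The angiotensin receptor gene Agtr2 was at least 152-fold, Spon1 at least 138-fold and Kng2 at least 140.3-fold lower.

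Sterol biosynthesis genes fell in 18 of 26 cases and rose in 1 (19 and 2 when adjusted over the list alone; median -1.59, adjusted p = 1.85e-05, and adjusted p = 0.034 with an estimated correlation). Tm7sf2 fell by 4.02 ± 0.32 and Acat2 by 2.84 ± 0.31. Cell cycle genes fell in 24 of 71 cases and rose in 4 (25 and 5 when adjusted over the list alone; median -0.57, adjusted p = 0.0113, and adjusted p = 0.161 with an estimated correlation), with Ccnd2 at -4.96 ± 0.68 and Tpx2 at 3.30 ± 0.39. That call was lost without replicate 2 (adjusted p = 0.0767) and with the spike-in scale (adjusted p = 0.1). Interferon genes rose in 11 of 32 cases and fell in 2 (13 and 2 when adjusted over the list alone; median 0.87, adjusted p = 0.00418, and adjusted p = 0.577 with an estimated correlation), with Oas1a up by 4.28 ± 0.60. The interferon median was 0.17 on slide 1, where the 60-day array stood at -0.47, against 1.54 and 1.28 on slides 2 and 3, whose 60-day arrays stood at 0.99 and 0.96. Inflammation genes rose in 3 of 21 cases and fell in 10 (3 and 11 when adjusted over the list alone; median -1.48, adjusted p = 0.0455, and adjusted p = 0.227 with an estimated correlation), with Serping1 at -5.27 ± 0.38. The inflammation call was lost without any array other than the 12-day arrays of replicates 2 and 3 and the 60-day array of replicate 2 (adjusted p up to 0.112) and with the spike-in scale (adjusted p = 0.102). Macrophage markers, not called as a list, had 4 rises and 9 falls among 18, with Lyz2 at -3.68 ± 0.42 and Lcp1 at least 5.76-fold higher.

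The remaining lists were not called. FSH and cAMP genes had 9 rises and 11 falls among 42 (Fos -4.62 ± 0.47), and androgen-responsive genes 7 and 3 among 17, with the early response genes Egr1 (-3.90 ± 0.37) and Egr2 (-4.63 ± 0.58) lower. Junction genes had 15 rises and 10 falls among 43, including cingulin, Cgn (4.66 ± 0.43), and Cdh1 (-4.70 ± 0.50). Glycolysis had 3 and 4 among 26 (median 0.10, mean -0.11, test up; Aldoc -3.54 ± 0.35), with the lactate dehydrogenase gene Ldha at 0.02 ± 0.30, and oxidative phosphorylation had 1 rise among 39. CDK inhibitors had 3 rises and 6 falls among 18, retinoid genes 3 and 3 among 20 (Aldh1a1 3.59 ± 0.35) and nuclear receptors 5 and 4 among 27 (median 0.09, mean -0.10, test up). Phagocytosis genes had 3 and 5 among 33, glutathione genes 7 and 2 among 32 (Gstm2 3.63 ± 0.44) and metal carriers 6 and 3 among 18. Leydig cell markers had 4 and 5 among 16 (median 0.21, mean -0.26, test down), endothelial markers 2 and 7 among 13 (Ramp2 -3.64 ± 0.35), red cell markers 1 and 3 among 6 and duct epithelium markers 3 and 5 among 10 (Krt7 -8.47 ± 0.82).

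The count of 7943 genes was 5044 without replicate 2. With the spike-in scale, 1674 genes were higher and 2464 lower, and 11 of 64 named rises, Inha and Sox9 among them, and 3 of 73 named falls lost their call. With only probes well above background on all 9 arrays, the immature Sertoli (adjusted p = 0.106), inflammation (0.227) and paracrine (0.149) lists lost their calls. The immature Sertoli and inflammation lists also lost them with quantile scaling (both 0.0544) and normexp (up to 0.185), and inflammation without the filter (0.0629) and with array weights (0.0542). Fabp9, Lum, Krt7 and Fshr were well above background on 1 of 3 arrays of the lower age, and Cst9l and Cst12 on 2, so the sizes of their changes are less certain.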

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

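Spike-in scaling and both forms of the normexp background correction were chosen only after the data were seen; all other alternatives were fixed before. Median and quantile scaling, the deposited table, no filter, other ways to choose probes, an intensity trend, array weights, and the arrays of the 2 ages alone left every total of called genes and lists within 1.5 times its value, though array weights gave 2089 higher genes for 12 against 5 days in place of 1379. With the replicate number as a block, 3977, 7684 and 9976 genes were called for 12 against 5, 60 against 12 and 60 against 5 days and 10617 over the 3 ages. Of the 2802, 5687 and 7943 genes called without it, 2802, 5686 and 7941 were among them. The block changed no list call and no named call other than the 7 it added; the slide as a random block has no list test. The cause was not tested for the changes below unless one is given. Leaving out replicate numbers leaves fewer arrays, which can lower counts. The counts of called genes were lowest without replicate 2 in all 3 comparisons. The 5-day and 60-day arrays of that replicate had the highest array weights (2.79 and 2.26).

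With spike-in scaling, 3018 genes were called for 60 against 12 days and 4138 for 60 against 5 days, the same numbers at least 2-fold, and 5373 over the 3 ages. The share of higher calls went from 48.4% to 86.8% between 12 and 60 days, because the scale itself moved. Clu was then at -0.22 for 12 against 5 days. That scale also added list calls by camera. They were endothelium (adjusted p = 0.0259) and Leydig cells (0.0183) for 12 against 5 days, inflammation (0.0188) for 60 against 12 days, and endothelium (0.0397) for 60 against 5 days. Normexp on median signals gave 45, 148 and 908 genes for the 3 comparisons, the same numbers at least 2-fold, and 633 over the 3 ages. A few spots of very high local background on the slide of replicate 3 (15, 7 and 42 per array) compressed its dim values: without them the 1st percentile of these arrays went from -0.51, -0.29 and -0.17 to -2.43, -1.87 and -2.53. Without those spots normexp gave 1556 genes for 12 against 5 days (1519 at least 2-fold), and at least 2-fold 3301 for 60 against 12 and 4871 for 60 against 5 days; Nr5a2 (-0.044) and Lrp2 (-0.021) then reversed for 60 against 5 days. The filter on all 9 arrays tests fewer genes and gave 1531, 3250 and 4483 calls (1517, 3086 and 4223 at least 2-fold) and 4687 over the 3 ages, without genes absent at 1 age. Lamb3 depends on its probe: for 12 against 5 days it was at 0.00 with that filter and 0.28 without the 5-day array of replicate 1, and without that array at 0.11 for 60 against 5 days; over all arrays and replicate numbers left out it ran from -5.88 to 0.28 and from -6.28 to 0.11.

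Camera with an estimated correlation called 2, 0 and 3 lists in place of 13, 17 and 13, and fry called 20 lists for 60 against 5 days but ended 2 list calls for 12 against 5 days. The filter on all 9 arrays ended 2 of 11, 5 of 16 and 3 of 12 list calls. Leaving out arrays or replicate numbers gave 1052 to 3146 genes for 12 against 5 days (1052 to 3138 at least 2-fold), 3041 to 5699 (3041 to 5593) for 60 against 12 and 5044 to 8006 (5044 to 7845) for 60 against 5 days. It gave 4868 to 7887 over the 3 ages, and 10 to 13, 11 to 17 and 11 to 13 lists. Signal over background limits genes dim at 1 age: 503, 1078 and 1793 of the called genes were not well above background on any array of the lower age.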

Other observations

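Tests of germ cell RNA, of a lower Sertoli share, of scaling as the whole cause or as the cause of the Sertoli part, and of dilution were chosen only after the results were seen, whereas those of array position or scaling and of other splits of the arrays were fixed before. Some genes named by the rule changed direction between the intervals, a grouping made after their values were seen. The nuclear receptor gene Nr4a3, an early target of cAMP, rose by 4.53 ± 0.36 from 5 to 12 days (adjusted p = 4.48e-05) and fell by 3.42 ± 0.36 from 12 to 60 days (adjusted p = 6.73e-05). Ppp1r14c, a phosphatase inhibitor, rose by 3.91 ± 0.33 and then fell by 4.71 ± 0.33. The opposite course was taken by the keratin gene Krt19, at least 5.42-fold lower at 12 than at 5 days and at least 18.8-fold higher at 60 than at 12 days. The macrophage marker Aif1 fell by 3.50 ± 0.47 and rose by 2.79 ± 0.47, and complement factor B, Cfb, was at least 12.2-fold lower and then at least 3.11-fold higher.

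Of the 61 measured spermatocyte and spermatid markers, 56 (91.8%) rose from 12 to 60 days, and no member of these lists stands in another list. Their brightest members at 60 days included Ldhc (5.69 ± 0.84 (SD, n = 3), against -2.70 ± 0.12 at 12 days), Mael (4.36 ± 0.57, against 0.65 ± 0.32) and Catsper2 (3.07 ± 0.47, against 0.18 ± 0.25), while Aurkc was bright at both (4.18 ± 0.64, against 3.58 ± 0.51) and not called. With the spike-in scale, which adds 0.94 to every gene in this comparison, their median was 4.66 (bootstrap SE 0.25). It was 5.32, 3.87 and 4.74 on slides 1, 2 and 3. Bootstrap SEs, here and below, come from resampling the members of a list and not the arrays. These values argue against scaling as the whole cause. The spike-in shift of -1.001 went down, whereas the bound set beforehand for position or scaling asked for a rise. It also lay outside the bound set against them, and array position stays tied to age. Of these markers, 5 of 26 and 8 of 35 lay above background on all arrays even at 5 days. Germ cells or their RNA in the 60-day cultures may account for the pattern, no sort that would remove them is named in the labels, and expression by adult Sertoli cells, an effect of age, was not tested.

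From 5 to 12 days the Sertoli list had a median of 2.14, while those of fibrillar matrix (-1.15), macrophages (-2.04) and endothelium (-1.14) lay below 0, of which endothelium was not called and the other 2 were called at the preset correlation but not with an estimated one (adjusted p = 0.127 and 0.0721); macrophage genes such as Laptm5 stood at 1.59 ± 0.42 (SD, n = 3) at 5 and -0.92 ± 0.18 at 12 days. The spike-in shift of 1.25 had been set beforehand as what scaling would show, but 1 factor per array moves every list alike and cannot part the Sertoli and macrophage lists by 4.18 (bootstrap SE 0.7). With the spike-in scale the Sertoli median was 0.86 (bootstrap SE 0.37), but -0.37, 2.11 and 0.52 on slides 1, 2 and 3, so scaling as the source of the Sertoli rise stays open. A lower share of Sertoli cells at 5 days would raise all other cell types alike. The spermatogonial and spermatocyte lists instead rose to 12 days (medians 1.722 and 1.545), so that share alone does not account for them. Neither list was called by camera with an estimated correlation (adjusted p = 0.195 and 0.0778). For 4 somatic lists a lower Sertoli share stays open. The widest gap among their medians, peritubular (-0.15) against macrophage, was 1.89 (bootstrap SE 0.68). The means of the same 2 lists were 0.62 apart. Peritubular markers were bright at 5 days, and the widest gap between medians was 1.61 (bootstrap SE 0.96) among the other 3. A change in the share or state of single cell types may contribute, 13 of the 26 Sertoli genes and 2 of the 18 macrophage genes stand in other lists, and array position stays tied to age.

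Sterol biosynthesis genes had a median of -1.59 from 5 to 60 days. Dilution of Sertoli RNA by germ cell RNA at 60 days would lower Sertoli genes as well. The Sertoli list lay above the sterol list by 4.04 (bootstrap SE 0.5). That gap cannot decide about dilution, because the Sertoli median had already risen by 2.14 from 5 to 12 days. From 12 to 60 days it changed by 0.74, or by -0.08 with only probes well above background on all 9 arrays. A rise of Sertoli genes with age could hide a dilution, so dilution stays open. With the spike-in scale the sterol median was -1.93 (bootstrap SE 0.22), and -2.54, -1.45 and -1.78 on slides 1, 2 and 3. These values argue against scaling as the whole cause. The spike-in shift of 0.24 lay inside the bound set beforehand against position or scaling, but slide 1 (0.92, against -0.285 and 0.02 on slides 2 and 3) did not, and position stays tied to age. A change of sterol synthesis in Sertoli cells with age and a loss of other sterol-making cells were not tested.

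The pairwise comparisons of 3 with 3 arrays have 10 splits, too few for a share under 0.1. The real split gave 2802, 5687 and 7943 genes (2801, 5619 and 7773 at least 2-fold) and the highest other split 1, 1 and 0, so 1 split of 10 gave as many in each case. For lists, 2, 1 and 2 of 10 splits gave as many as the real 13, 17 and 13, with 14, 12 and 13 in the highest other. Of those, the 3 other splits that part all 3 slides gave 0 genes each and up to 14, 12 and 13 lists. Over the 3 ages, 1 of 100 splits drawn from 280 gave 8233 genes, the real one, and the highest other 5767. As the numbers pair the arrays, the 36 splits that keep 1 array of every slide in each group were also run: 1 gave as many, the real one, and the highest other 4113. For this count chance is therefore an unlikely cause, though so few splits cannot exclude it. The pairwise gene counts and the list counts stay undecided.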
